A study of Aspergillus nidulans with 24 samples.

How the data were processed

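RNA was measured in mycelium of Aspergillus nidulans, a filamentous fungus, from 2 strains grown in 4 media, with 3 biological replicates in each of the 8 groups and 24 libraries in all. The deletion strain lacks areB, the gene of the GATA-type transcription factor AreB, and the control strain, called wild type below, carries it. Cultures grew for 9 to 11 h at 37 °C on 0.1 % fructose, which does not repress use of other carbon sources, or on 1 % glucose, which does. The nitrogen source was 5 mM urea, which does not repress use of other nitrogen sources, or 10 mM ammonium tartrate, which does. By the labels only the ammonium media held tartrate, so effects of ammonium and of tartrate cannot be told apart. The sugars also differed in concentration, so effects of the kind of sugar and of its amount cannot be told apart. The labels give the range of 9 to 11 h for every library and not the time of each. Total RNA was depleted of ribosomal RNA, amplified for 14 cycles and sequenced as paired reads of 100 bp. The genotype labels show that the deletion strain also lacks nkuA, an end-joining repair gene, and differs from the control at the marker loci pyrG, argB, pabaB, riboB and biA, so strain background and areB deletion are confounded for every gene.

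Only 1 table of the whole series was used, with 8728 genes, of which 1483 carried a symbol. It holds the authors' fold change, a ratio of areB deletion over wild type within each medium, the authors' p-value, adjusted for multiple testing over genes before the table was deposited, for each of the 4 comparisons, and the authors' signal for each group, a mean of normalized counts over its libraries. Per the submitters' processing notes the tools were FastQC, Trimmomatic, GATK, HTSeq 0.9.1 and DESeq2 1.16.1. The aligner, the genome build and the annotation are not given in the sources used here. Values per library were not used here, so total counts per sample, the spread between replicates and the limit that a count of 0 allows are unknown, and no replicate could be examined on its own. As the authors deposited them, the sums of the mean normalized counts ran from 2.75e+06 in the deletion strain on fructose with urea to 3.01e+06 in the wild type on glucose with ammonium.

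A gene was called changed when the authors' adjusted p was under 0.05, and counts are also given with an absolute log2 fold change of at least 1. All 4 comparisons held an adjusted p for the same 8639 genes and none for the other 89. The deposited fold changes were moderated: among genes with a ratio of group means beyond 1 on the log2 scale and means above 5, the deposited log2 fold change kept a median of 0.807 of that ratio on fructose with urea and 0.848 on glucose with ammonium. A p was recovered from each adjusted p by inverting the step-up adjustment of Benjamini and Hochberg, and a standard error from the log2 fold change over the normal deviate of that p. Where the adjusted p fixed a gene's deviate only loosely, its standard error was borrowed from its other comparisons, and 8512 genes had one. On glucose 7410 genes with urea and 7362 with ammonium had an adjusted p of 1, only 1229 with urea and 1277 with ammonium had their own standard error, and the rest were borrowed. Where 2 comparisons both gave an own standard error, these agreed within 0.1 on the log2 scale for 98.9 % of 7140 genes between the fructose media and for 92.4 to 96.1 % of 665 to 1246 genes in pairs with a glucose medium. The agreement was unchecked for most genes on glucose. All standard errors printed are recovered ones.

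The difference of the deletion effect between 2 media was tested per gene, 2-sided, as the difference of the log2 fold changes over the root of their summed squared standard errors, adjusted by Benjamini and Hochberg over 8512 genes. The overlap of changed genes was set against independent lists with a 2-sided Fisher's exact test. Pearson and Spearman coefficients of log2 fold changes were computed across the 7759 genes with a mean of at least 10, 82 of them without an adjusted p. Genes are not independent replicates. Of 35 gene lists written before the data were examined, 30 had at least 4 members with a standard error and were tested in each medium, 120 tests in all, with limma's cameraPR on the signed deviate, a preset inter-gene correlation of 0.01 and adjustment over all 120. No correlation could be estimated without values per library, and 0.05 was the alternative. List members were matched by symbol, 307 in the table and 3 through the reference, and 134 symbols were not matched. Neighbouring genes were read from the RefSeq annotation of assembly ASM1142v1, to which 8257 of the 8728 identifiers were matched. The build of the table is not given in the sources used here, so no coordinates are printed.

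Named genes followed a rule fixed before the data were examined. It took the strain markers. It took up to 10 genes with the largest rise and 10 with the largest fall per medium among those called, with a mean of at least 50 and a symbol. It took up to 4 members per list and medium with the smallest adjusted p, and the nitrogen and carbon regulators. It took the 10 largest changes among genes called in all 4 media, and the 2 largest on either side with a systematic identifier. Genes without a surely known function were left out of the text at will. Genes named outside it are said to be so.

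The method was tested on simulated data of the same size. Own or borrowed standard errors lay within 15 % of the simulated ones for at least 99.95 % of the 8292 simulated genes that had one. The simulated errors were those recovered from the data, borrowed ones included, so this did not test whether borrowing holds. Nor did the simulation test whether the recovered errors were of the right size. The difference test between fructose with urea and glucose with urea called 12.3 % of simulated differences of 1 on the log2 scale, 38.7 % of those of 2 and 64.4 % of those of 3, and 4 of 8312 genes without a difference. Lists of 15 genes had a p under 0.05 in 4 % of cases without a shift and in 86 % of cases shifted by 1 deviate. The simulated genes varied independently of each other, so these shares do not hold for lists of correlated genes. Alternatives were a threshold of 0.01, log2 fold changes of at least 1 and 2, a mean of at least 10, a recomputed adjustment, recentred log2 fold changes, and other settings of the list test and of the correlation. Alternatives chosen after the data were seen are named as such in the closing section. Comparisons of media within a strain were not tested, since the table holds none. The versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.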

Results

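The series compares gene expression in Aspergillus nidulans with and without areB across a carbon source that represses or does not repress, crossed with a nitrogen source that represses or does not repress. Each of the 8 groups held 3 libraries. Group levels are the authors' means of normalized counts, and values after ± are recovered standard errors of the log2 fold change of areB deletion over wild type. No errors of group means or depths per library were used here, so no level carries an error of its own.

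The strain markers served as a check of the labels. The authors' deposited table listed areB at 0 in all 4 deletion groups, against wild type means of 67.9 on fructose with urea, 75.4 on fructose with ammonium, 93.9 on glucose with urea and 73.5 on glucose with ammonium. In the authors' deposited table nkuA was likewise listed at 0 in all 4 deletion groups, against wild type means from 103 to 137. The orotidine phosphate decarboxylase gene pyrG had a log2 fold change of 1.22 ± 0.54 on fructose with urea in the authors' deposited table, with an adjusted p of 0.29. None of pyrG, argB, pabaA, pabaB, riboB and biA passed the threshold in any medium in the authors' deposited table.

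On fructose with urea, where neither source represses, the urease gene ureB and the ethanol cluster genes alcS and alcM were higher in the deletion strain, and prnD of proline use and the sexual development genes esdC and mutA were lower. The authors' deposited table gave ureB, of the urease system, a log2 fold change of 1.28 ± 0.33 (adjusted p 0.0080), with means of 1228 in the deletion strain and 487 in the wild type. The gene furG, with homology to a yeast uracil transporter, rose by 2.38 ± 0.63 (adjusted p 0.011) and lamB, which takes part in lactam use, by 1.60 ± 0.41 (adjusted p 0.0080) in the authors' deposited table. Of the ethanol use cluster, alcS rose by 3.18 ± 0.70 (adjusted p 0.00089) and alcM by 2.89 ± 0.78 (adjusted p 0.016) in the authors' deposited table, from wild type means of 1.62 and 0.715. The putative proline dehydrogenase gene prnD had a log2 fold change of -3.59 ± 0.80 (adjusted p 0.0010) in the authors' deposited table, with means of 16.0 against 836. In all, 192 of 8639 genes were called, 72 higher and 120 lower, and 167 of them with an absolute log2 fold change of at least 1.

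The gene lists in fructose with urea moved as follows. Of the 17 members of the sexual development list with an adjusted p, 2 fell and 15 did not pass, 3 fell adjusted over the list alone, the median log2 fold change was -0.65, and cameraPR placed the list below other genes (adjusted p 0.0048). With a preset correlation of 0.05 that adjusted p was 0.064. The members that fell in the authors' deposited table were esdC, an early sexual development gene, at -2.69 ± 0.77 (adjusted p 0.029), and mutA, a mutanase of fruiting body formation, at -2.87 ± 0.80 (adjusted p 0.022), the latter from a wild type mean of only 13.7. The zinc cluster regulator gene nosA stood at -2.39 ± 0.76 (adjusted p 0.069) in the authors' deposited table. Of 15 amino acid and amide catabolism genes with an adjusted p, lamB rose and prnD fell, 1 rose and 5 fell adjusted over the list alone, and the list test gave an adjusted p of 0.26. The test left out 5 of the 20 measured members, hpdA, hmgA, fahA, maiA and fmdS, named here outside the rule, which had no adjusted p and all had lower means in the deletion strain, from 61.1 against 306 for fmdS to 7.22 against 2947 for hpdA in the authors' deposited table. Of 6 autolysis genes, the chitinase gene chiB fell, at -1.82 ± 0.49 (adjusted p 0.015) in the authors' deposited table, 3 fell adjusted over the list alone, and the list test gave 0.063. Of 9 ethanol use genes, 2 rose, 3 did adjusted over the list alone, and the list test gave 0.063. Of 17 urea and purine genes, 2 rose by both adjustments, and the list test gave 0.42.

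Other named genes that changed on fructose with urea were a light response regulator gene, silA, at -2.54 ± 0.71 (adjusted p 0.022), the pH sensor gene palH at -0.72 ± 0.22 (adjusted p 0.039) and the cytochrome P450 gene CYP646A1 at 1.20 ± 0.31 (adjusted p 0.0085) in the authors' deposited table. The largest rises by systematic identifier were AN8614 at 4.44 and AN7954 at 4.34 on the log2 scale in the authors' deposited table, and the largest falls were AN5067 and AN5068, both listed at 0 in the deletion strain in this medium.

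On fructose with ammonium, where only nitrogen represses, the genes of iron uptake and siderophore synthesis lay below other genes in the deletion strain. Of the 15 measured members, 1 fell past the threshold over all genes and 4 adjusted over the list alone, 14 had a log2 fold change below 0, the median was -0.94, and cameraPR gave an adjusted p of 0.0011. With a preset correlation of 0.05 it was 0.020. The member that fell was amc-1, a mitochondrial carrier, at -1.38 ± 0.41 (adjusted p 0.037) in the authors' deposited table. The siderophore transporter gene mirB stood at -1.78 (adjusted p 0.16), with means of 79.1 against 457, and the regulator gene hapX at -1.64 (adjusted p 0.092) in the authors' deposited table. Outside the list, ngn26, annotated as the ortholog of a siderophore transacetylase gene, fell, at -2.67 ± 0.63 (adjusted p 0.0027) in the authors' deposited table.

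The alcohol dehydrogenase gene alcA rose by 2.52 ± 0.68 (adjusted p 0.015) on fructose with ammonium in the authors' deposited table, from a wild type mean of 79.0 to 716. A secreted thaumatin-like protein gene, cetA, rose by 2.83 ± 0.64 (adjusted p 0.0012) and the putative potassium ATPase gene enaA by 2.28 ± 0.60 (adjusted p 0.011) in the authors' deposited table. Among the genes that fell in the authors' deposited table were pkfC, annotated in the aspernidine A cluster, at -2.32 ± 0.38 (adjusted p 5.1e-07), the thioredoxin reductase gene trxB at -2.49 ± 0.64 (adjusted p 0.0074) and gprK, a G-protein coupled receptor gene, at -2.14 ± 0.57 (adjusted p 0.013). The putative transglycosidase gene gelB was the 1 of 17 cell wall synthesis genes that fell, at -2.01 ± 0.50 (adjusted p 0.0054), and the molybdenum cofactor gene cnxH the 1 of 11 nitrate assimilation genes, at -0.76 ± 0.21 (adjusted p 0.021), in the authors' deposited table. Adjusted over the list alone the counts were again 1 and 1, and the list tests gave adjusted p of 0.42 and 0.84. In all, 217 genes were called, 97 higher and 120 lower, 181 of them with an absolute log2 fold change of at least 1.

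On glucose with urea, where only carbon represses, more genes rose than fell, 120 against 42, and 146 of the 162 had an absolute log2 fold change of at least 1. The dihydroxybenzoate decarboxylase gene dhbD rose by 3.17 ± 0.76 (adjusted p 0.0029) and CYP623B2, a cytochrome P450 gene, by 1.99 ± 0.42 (adjusted p 0.00026) in the authors' deposited table. The gene furG rose by 3.00 ± 0.65 (adjusted p 0.00042) and alcA by 2.37 ± 0.69 (adjusted p 0.036) in the authors' deposited table, the latter from a wild type mean of 4.60 to 67.1. A dehydrin-like protein gene, dlpA, rose by 2.25 ± 0.61 (adjusted p 0.017) and the phosphoketolase gene phk by 1.78 ± 0.50 (adjusted p 0.024) in the authors' deposited table. The named genes that fell in the authors' deposited table included trxB at -2.27 ± 0.64 (adjusted p 0.024). Apart from the strain markers, the GATA factor list alone passed the list test in this medium, with an adjusted p of 0.036 that was 0.91 without areB.

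On glucose with ammonium, where both sources repress, 165 genes were called, 92 higher and 73 lower, 148 of them with an absolute log2 fold change of at least 1. The rises of dhbD, at 3.16 ± 0.76 (adjusted p 0.0032), and CYP623B2, at 1.99 ± 0.42 (adjusted p 0.00030), were of the same size as on glucose with urea in the authors' deposited table. Among genes with a symbol other than areB and nkuA, large falls were those of atrA, a drug transporter gene, at -3.52 ± 0.72 (adjusted p 0.00015), and trxB at -3.47 ± 0.64 (adjusted p 1.1e-05) in the authors' deposited table. The putative transglycosidase gene gelD was at -2.01 ± 0.43 (adjusted p 0.00046) and cnxH at -0.81 ± 0.20 (adjusted p 0.0056) in the authors' deposited table. Of 33 genes of secondary metabolite clusters none passed over all genes, 30 of the 32 tested as a list had a log2 fold change above 0, the median was 0.39, and cameraPR gave an adjusted p of 0.044. With a preset correlation of 0.05 it was 0.30, and on recentred log2 fold changes 0.062.

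The regulators of nitrogen and carbon use other than areB did not pass the threshold in any medium. The GATA factor gene areA had log2 fold changes of 0.14, -0.52, 0.06 and 0.21 on fructose with urea, fructose with ammonium, glucose with urea and glucose with ammonium in the authors' deposited table. The co-repressor gene nmrA had 0.08, 0.05, 0.06 and -0.49 in the authors' deposited table, and the zipper gene meaB had -1.06, -1.54, -0.33 and 0.09. The carbon repressor gene creA had -1.45, -2.04, 0.47 and -0.23 in the authors' deposited table, with its smallest adjusted p, 0.058, on fructose with ammonium. No member passed over all genes, in any medium, among 28 plant polysaccharide hydrolases, 11 genes of glycolysis, 13 of the glyoxylate cycle and gluconeogenesis, 7 of ammonium and glutamate metabolism and 18 of conidiation. Nor did any of 18 genes drawn by words for ribosomal proteins in their product description, which can take in other genes. Adjusted over the list alone, 2 genes of the glyoxylate cycle and gluconeogenesis and 2 of conidiation fell on fructose with ammonium, and none of the other 4 lists had any. Of 9 nitrogen regulators 1 besides areB, meaB, and of 8 carbon regulators 1, creA, fell adjusted over the list alone on fructose with ammonium.

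The larger lists, drawn by words in the product descriptions, passed no list test. Such a match can also take in genes of another kind. Of 59 cytochrome P450 genes with an adjusted p, 2 rose on fructose with urea, 1 fell on fructose with ammonium, 1 rose on glucose with urea and 2 rose on glucose with ammonium. Adjusted over the list alone these counts were 2, 1, 1 and 3 in the same directions, with 1 more fall on glucose with ammonium. Of 72 glycoside hydrolase genes, 1 rose and 3 fell on fructose with urea, where 1 rose and 7 fell adjusted over the list alone. In the same list 1 rose and 1 fell on fructose with ammonium, 2 rose and 1 fell on glucose with urea, and 1 rose and 1 fell on glucose with ammonium. Adjusted over the list alone these were 1 and 1, 2 and 2, and 2 and 1. Of 115 genes with peptidase or protease in their product description, 1 fell on fructose with urea, 2 on fructose with ammonium and 1 in each glucose medium. Adjusted over the list alone the falls numbered 1, 3, 1 and 1, with 1 rise on fructose with ammonium. Of 46 proteasome genes 1 rose on fructose with ammonium, where 1 rose and 1 fell adjusted over the list alone. The 6 extracellular protease genes with an adjusted p all had log2 fold changes below 0 on fructose with ammonium, with a median of -1.02, none changed by either adjustment, and the list test gave an adjusted p of 0.063. The lists of amino acid permeases, arginine and proline synthesis, sterigmatocystin, penicillin and respiration were too small to test, and none of their matched members passed over all genes. Most symbols of the sterigmatocystin, respiration and arginine and proline lists were not matched, so most of those genes were not examined. Adjusted over the list alone, 2 of the 3 penicillin cluster genes fell on fructose with ammonium.

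The counts of called genes cannot be ranked between the carbon sources. The robust SD of the recovered deviates was 1.18 on fructose with urea, 1.21 on fructose with ammonium, 0.82 on glucose with urea and 0.84 on glucose with ammonium, where 1 is the value for unchanged genes with exact errors. On glucose most of these deviates rest on standard errors borrowed from other comparisons, since only 1229 genes with urea and 1277 with ammonium had their own. With the deviates divided by it, a setting chosen after the data were seen, 84 and 76 genes were called on fructose and 334 and 293 on glucose, which turned the order.

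**Figure D1:**
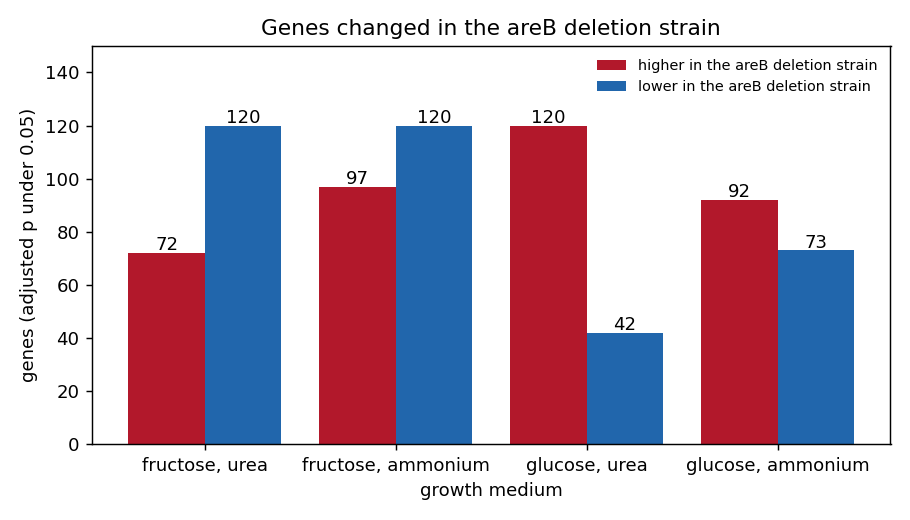
Genes called in the areB deletion strain (y axis, count at an adjusted p under 0.05) in each of the 4 media (x axis), split into higher and lower than the wild type. Falls were 120 in each fructose medium, against 42 and 73 in the glucose media. With deviates divided by their robust SD, a setting chosen after the data were seen, the falls were 46 and 40 on fructose and 103 and 132 on glucose.

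**Figure D2:**
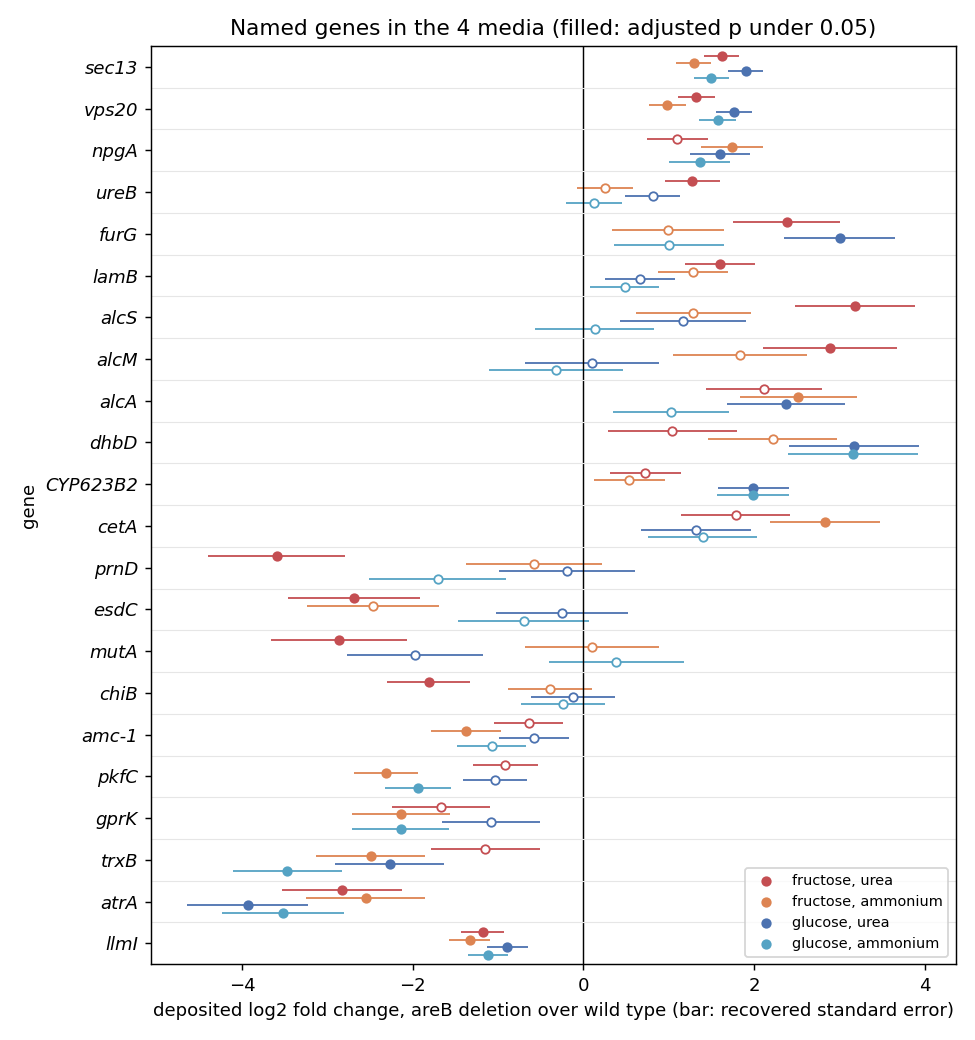
Deposited log2 fold changes of areB deletion over wild type (x axis) of 22 named genes (y axis) in the 4 media, with bars for the recovered standard error and filled points for an adjusted p under 0.05. The rises of sec13 and vps20 and the falls of atrA and llmI passed in all 4 media.

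**Figure D3:**
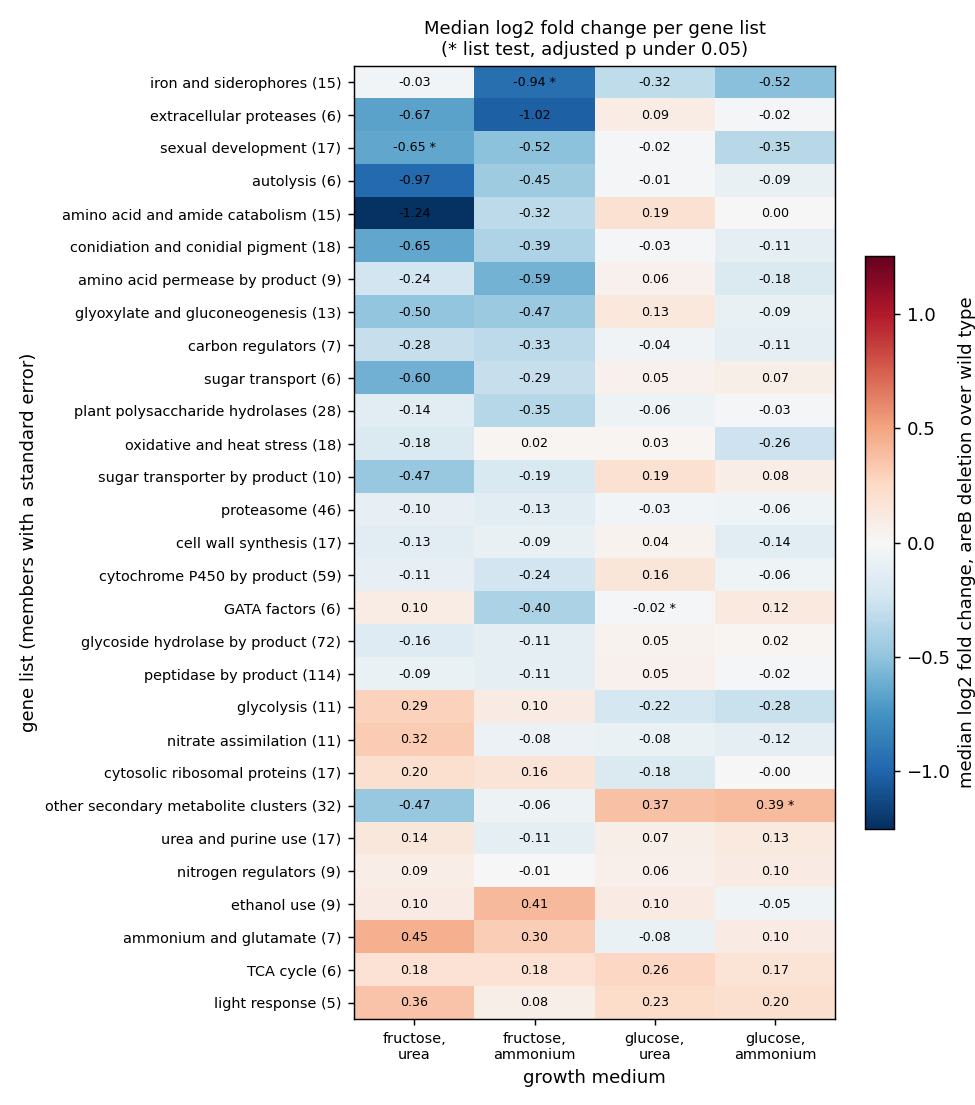
Median log2 fold change of areB deletion over wild type (colour and number) of 29 gene lists (y axis, with the number of members tested) in the 4 media (x axis), with an asterisk for a list test with an adjusted p under 0.05. The asterisks stand at iron and siderophores on fructose with ammonium, sexual development on fructose with urea, secondary metabolite clusters on glucose with ammonium, and GATA factors, which hold areB itself, on glucose with urea.

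The overlap of the 4 comparisons shows how far the deletion strain differed from the wild type in every medium. Of 402 genes called in at least 1 medium, 222 were called in 1, 83 in 2, 40 in 3 and 57 in all 4, where 29 were higher and 28 lower. No gene was called in opposite directions. Each pair of media shared 32 to 62 called genes per direction, where independent lists would share 0.355 to 1.67, with a Fisher's exact p of at most 2.6e-49. Genes are not independent replicates, and every comparison set the same strains against each other. The p-values of overlap here and below therefore only describe its extent. Of the 28 genes lower in all 4 media, 13 belonged to 1 stretch of chromosome III, and 4 more, areB, nkuA, AN12279 and AN12280, were listed at 0 in all deletion groups, which leaves 11. Without the stretch and the genes at 0, a setting chosen after the data were seen, pairs of media shared 14 to 40 genes that fell, where independent lists would share 0.145 to 1.10, with a Fisher's exact p of at most 1.9e-21. The rises shared were unaltered, at 38 to 62. Across genes, Pearson's r of the log2 fold changes was 0.81 (Spearman's rho 0.75) between the fructose media and 0.79 (rho 0.59) between the glucose media. Between a fructose and a glucose medium Pearson's r ran from 0.52 to 0.69 and rho from 0.34 to 0.58. With the called genes left out, r between fructose with urea and glucose with urea was 0.31.

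Among the genes higher in all 4 media, sec13, of the vesicle coat and the nuclear pore, rose by 1.62 ± 0.20, 1.29 ± 0.20 and 1.90 ± 0.20 on fructose with urea, fructose with ammonium and glucose with urea in the authors' deposited table, and on glucose with ammonium from a mean of 332 to 953 (adjusted p 7.6e-11). The endosomal sorting gene vps20 rose by 1.32, 0.99, 1.76 and 1.57 in the authors' deposited table, with adjusted p of at most 0.00061. The phosphopantetheinyl transferase gene npgA rose in 3 of the media, by 1.74 on fructose with ammonium, 1.60 on glucose with urea and 1.36 on glucose with ammonium in the authors' deposited table. Among genes lower in all 4 media in the authors' deposited table, llmI, a LaeA-like methyltransferase gene, had -1.18, -1.33, -0.89 and -1.12, and atrA had -2.83, -2.55, -3.94 and -3.52.

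The 10 largest changes shared by all 4 media were all falls. They comprised areB, nkuA, AN12280 and 7 genes that lie near each other at the start of chromosome III in the RefSeq order of assembly ASM1142v1, namely AN5067, AN5068, AN5069, AN5078, AN5079, AN5082 and AN10625. The first 23 measured genes of that chromosome in this order, a stretch of 33 annotated genes, had means under 1 in all 4 deletion groups in the authors' deposited table, and 22 of them were listed at 0 throughout. The exception, AN5068, had a mean of 0.373 in the deletion strain on fructose with ammonium in the authors' deposited table, against 1399 in the wild type. Wild type means of AN5067, annotated as a putative transporter, ran from 691 to 1707 in the authors' deposited table. The next measured gene, AN5060, named outside the rule for its place, had means of 93.7 in the deletion strain and 24.5 in the wild type on fructose with urea in the authors' deposited table. The stretch, which was noticed after the data were seen, contributed 21, 16, 14 and 17 of the genes called lower on fructose with urea, fructose with ammonium, glucose with urea and glucose with ammonium.

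**Figure D4:**
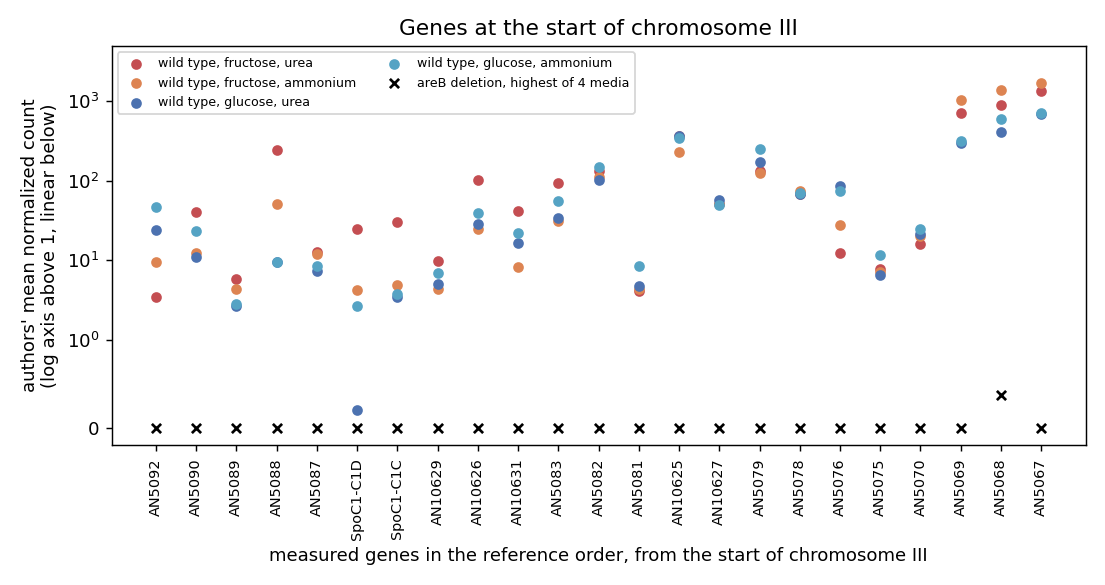
Authors' mean normalized counts (y axis, logarithmic above 1 and linear below) of the first 23 measured genes of chromosome III in the reference order (x axis), with a coloured point for each wild type group and a cross for the highest of the 4 deletion groups. All crosses but that of AN5068, at 0.373, lie at 0, while the wild type reached 1707.

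Whether the effect of the deletion depended on the medium was tested per gene as a difference of log2 fold changes. No gene passed in any of the 4 tests at an adjusted p under 0.05 with this z test, and the genes at an unadjusted p under 0.05 numbered 250 for fructose with urea against glucose with urea, 112 for fructose with ammonium against glucose with ammonium, 54 for urea against ammonium on fructose and 68 for urea against ammonium on glucose. Chance alone would give 426 of 8512. The robust SD of z was 0.89, 0.67, 0.58 and 0.52 in the same order, below the value of 1 for unchanged genes with exact errors. Most errors on glucose were borrowed, but 7140 genes had their own in both fructose media. Borrowing alone thus does not account for the 0.58 between the fructose media. With z divided by its robust SD, a setting chosen after the data were seen, 0, 9, 39 and 130 genes were called. The smallest adjusted p was 0.53, for the putative heat shock protein gene AN5781, which is outside the rule for named genes and whose log2 fold change was lower by 3.41 ± 0.85 with urea than with ammonium on fructose, a difference of -3.41. In the simulated data the test of the carbon source with urea called 12.3 % of differences of 1 on the log2 scale. It called 38.7 % of those of 2. The simulated estimates were drawn with the recovered errors, so these shares need not hold for the narrower z of the data. No difference by nitrogen source was simulated. Genes past the threshold in 1 medium and not in another, such as prnD, ureB and dhbD, were therefore neither shown to differ between media nor shown to be alike.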

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

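Tests of lists on the difference between media, and of all explanations except uneven replicates and a fructose response of both strains, were chosen only after the results were seen. The lists of the report were also tested with cameraPR on the difference of the deletion effect between media, and 7 of the 120 tests passed an adjusted p of 0.05. On fructose the log2 fold changes of the iron and siderophore genes were higher with urea than with ammonium, by a median of 1.01 (adjusted p 1.3e-05). The medium with ammonium was the one where this list lay below other genes. With urea the log2 fold changes of the sexual development genes were lower on fructose than on glucose, with a median difference of -0.65 (adjusted p 0.0027). The same held, each with an adjusted p of 0.030, for the glyoxylate and gluconeogenesis genes (median -0.79), the autolysis genes (-1.07) and the secondary metabolite cluster genes (-0.82). With ammonium the log2 fold changes were lower on fructose than on glucose for the extracellular protease genes (-0.84) and the secondary metabolite cluster genes (-0.50), with adjusted p of 0.030 each. With a preset correlation of 0.05 only the iron and siderophore genes passed, with an adjusted p of 0.0016, and sexual development had 0.062. Outliers among libraries, and other splits of the libraries into groups, were not examined, since no values per library were used here.

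The stretch at the start of chromosome III was examined for a cause in the strain. Against removal together with areB or nkuA, 0 of its genes lie on chromosome I or IV, where those genes lie. A segment missing from the genome of the deletion strain would leave every gene between the first and the last without reads, and 23 of 23 had means under 1, but 22 of them had been chosen for being at 0. For loss of AreB as an activator, 3 genes placed elsewhere and named for it, AN0012, AN4826 and mrvB, were also listed at 0 in the deletion groups in the authors' deposited table, with wild type means of at most 8.38, and so were AN12279 and AN12280, whose place is unknown, with wild type means from 48.6 to 220. A missing segment and a loss of activation cannot be told apart, since strain and areB deletion are confounded and DNA was not analysed here.

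The 89 genes without an adjusted p held a signal that the comparisons could not use, and 82 of them had their highest mean in a wild type fructose group, 92.1 %, against 36.5 % of the genes with one (2-sided Fisher's exact p 7.8e-28). A low-count filter would need low means, and 92.1 % of the 89 genes had a mean of at least 10. Uneven wild type fructose replicates would lower the share of the ratio of means that the moderated log2 fold change kept, and the median share on fructose with urea was 0.615, against 0.767 in tested genes with as large a fall and a bound of 0.520 set beforehand. That bound was missed, as was the bound of 0.509 on fructose with ammonium, where the share was 0.592, but the explanation was left open by a rule changed after the values were seen, since 1 spread per gene is shared by all 24 libraries and 1 far library in 1 of 8 groups need not bring the share under the lowest 5 %. A fructose response of both strains could bear on where these genes were highest, not on why they had no adjusted p. It also stayed open. In the deletion strain 65.9 % of the 82 genes were higher on fructose than on glucose with both nitrogen sources.

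Called genes outside that stretch lay next to each other more often than chance order gave, with 28 neighbouring pairs called the same way against a mean of 8 and a highest of 19 in 10000 random orders, so that p was 0.0001, the smallest they can give. The runs of 3 or more were AN7952 to furG, higher, AN8134 to AN8137, lower, and alcS, alcM and alcA, higher, all named after their values were seen. A copy number change would move a run alike in every medium, and the highest and lowest of the 4 media differed by more than 2.57 standard errors, the bound for a range of 4, in 1 of the 3 runs, AN7952 to furG (3.49 on glucose with urea, 0.79 on glucose with ammonium), and not for AN8134 to AN8137 (-0.50 on fructose with urea, -2.55 on glucose with ammonium) or alcS to alcA (2.73 on fructose with urea, 0.28 on glucose with ammonium). The other 2 gaps, 2.05 ± 0.91 and 2.45 ± 1.02, were larger than the 0.5 a copy number change was taken to allow, but with these errors and runs picked for their calls it stayed open. Regulation of clusters by AreB or by another locus of the strain is a candidate explanation that stayed untested.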

How the results depend on the processing

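Settings named as divided by the robust SD, the log2 ratio of group means, and settings that leave out areB, nkuA, genes at 0, the stretch of chromosome III or genes highest in a wild type fructose group, were chosen after seeing the data. No paired analysis was possible because the table held no values per library; for the same reason another normalization, no filter, a fit of each medium alone, leaving out a replicate and an interaction fit were not run. Counts for fructose with urea, fructose with ammonium and glucose with urea were 110, 109 and 107 at an adjusted p under 0.01, and 100, 93 and 78 with a log2 fold change of at least 2, where glucose with ammonium had 81. These follow from the stricter thresholds. With deviates divided by their robust SD the 4 counts were 84, 76, 334 and 293, and the cause was not tested. Leaving out genes highest in a wild type fructose group gave 108 on fructose with urea, by construction, since that filter can hardly remove a rise on fructose (72 of 72 stayed, and 36 of 120 falls). Counts with a log2 fold change of at least 1, a mean of at least 10, a recomputed adjustment, recentred log2 fold changes, or without areB, nkuA and genes at 0 stayed within 1.5 times. The tests of a difference stayed at 0 genes under every planned setting and with the log2 ratio of group means, and with deviates divided by their robust SD called 9, 39 and 130 genes for the carbon source with ammonium, the nitrogen source on fructose and the nitrogen source on glucose; the cause was not tested.

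Genes called in at least 1 medium numbered 222 at an adjusted p under 0.01, and the count of opposite directions stayed at 0 in every setting. Without areB, nkuA, genes at 0 and the stretch of chromosome III, 375 were called in at least 1 medium and 40 in all 4. With called genes left out, Pearson's r was 0.31 and 0.38 for fructose with urea against glucose with urea and with ammonium. It was 0.40 and 0.53 for fructose with ammonium against the same, and 0.64 between the glucose media. A lower r can follow from leaving out large values. The 82 genes with a mean of at least 10 and no adjusted p stayed in. Of the list tests, 8 passed in the main setting, 5 with a correlation of 0.05, 4 with ranks, 15 with the log2 fold change as the statistic, 4 without the member with the largest deviate and 2 without areB and nkuA. Without areB and nkuA the strain markers changed sign on fructose with urea (adjusted p 0.87) and on fructose with ammonium (0.91), and so did the GATA factors on glucose with urea (0.91; 0.97 without the member with the largest deviate, which is areB). Those lists rested on the deleted genes. Iron and siderophores on fructose with ammonium kept an adjusted p under 0.05 in all 6 alternatives, from 0.00035 to 0.020. That list holds neither areB nor nkuA, so leaving these out could alter only the adjustment and was no check of it. All the alternatives rested on the same deposited comparisons and a preset inter-gene correlation. None could show whether the members moved together in 1 library. Of 138 calls of 66 named genes, 106 stayed past 0.01, 134 with a mean of at least 10, 106 with deviates divided by their robust SD, and all 138 in the recentred and recomputed settings. Depth per library was unknown, and 3 libraries per group limited the precision.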

Other observations

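No test reported in this part was planned. Genes of phenylalanine and tyrosine breakdown that lie close together had no adjusted p, and their levels differed most on fructose. The authors' deposited table gave hpdA means of 2947 in the wild type and 7.22 in the deletion strain on fructose with urea, and 2225 against 9.56 on fructose with ammonium. For hmgA the authors' deposited table gave 2278 against 51.3 and 1631 against 59.8, and for fahA 634 against 14.1 and 549 against 22.7. On glucose all of these means were at most 11.2 in the authors' deposited table. The cytochrome P450 gene CYP548D1 had 5797 against 50.6 on fructose with urea, and the sexual development regulator gene rosA 221 against 8.66, in the authors' deposited table. None of these genes was tested, their replicates were not seen, and they were chosen after their values were seen.

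A group of genes was high only where fructose met ammonium tartrate. In the authors' deposited table AN4003, annotated as a putative tartrate dehydrogenase gene, had means of 9491 in the wild type and 2070 in the deletion strain on fructose with ammonium, and at most 36.0 in the other 6 groups. The neighbours AN5029, AN5030, mdhB and AN5032 had wild type means of 563, 2343, 948 and 860 there in the authors' deposited table, against 47.5, 324, 77.4 and 87.2 in the deletion strain, and at most 1.34 elsewhere. A gene annotated as a glyceraldehyde-3-phosphate dehydrogenase, gpdC, had 2215 against 131 in that medium in the authors' deposited table. These genes too had no adjusted p, and they were chosen after their values were seen.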
